A study of Arabidopsis thaliana with 4 samples.

How the data were processed

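Transcript levels were measured on Affymetrix GeneChips in mesophyll protoplasts, which are leaf cells freed of their walls by enzymes. In each experiment, protoplasts received either control plasmid DNA or a plasmid for KIN10 (AT3G01090), a catalytic subunit of the energy-sensing kinase SnRK1, and were kept in the light for 6 h. There were 4 arrays in all, 2 with control DNA and 2 with KIN10. Per the labels' protocols, protoplasts from 36 plants were pooled for each pair, each transfection used 1 mg of DNA, and 8 ug of total RNA was labelled per array. Per the labels, the replicate number marks an experiment done independently, with its own plants, growth chamber, DNA, operator and array facility.

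The deposited values are linear probe set intensity values, and GCOS 1.0 is the only tool named in the submitters' processing notes. The settings of that software are not given in the sources used here. In the deposited table the mean intensity, after trimming 2% of values at each end, lay between 1500.13 and 1500.15 on every array, so each array had been put on a common scale with a single factor. Detection calls were not used here. The median signal was 490 on control array 1, 522 on KIN10 array 1, 344 on control array 2 and 276 on KIN10 array 2, and the 10th percentile was 26.7, 31.4, 11.9 and 10.4 in that order. With 2 arrays per group, the number of arrays limits the precision.

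From these values the log2 signal was taken, after 1 value at or below 0 had been replaced by the smallest positive value of its array. The 64 Affymetrix control probe sets were set apart, and each array was centred on the median of the other 22746. Probe sets whose mean log2 signal over the 4 arrays lay below the 40th percentile were removed, which left 13648 for the test and took out 9098. The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with the experiment as a block, 1 residual degree of freedom and Benjamini-Hochberg adjustment over the 13648 probe sets. A probe set was called at an adjusted p under 0.05.

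The block follows the design text, which describes each control and KIN10 transfection as a pair. Arrays with the same number also deviated together from their group means, with a Pearson r of 0.705 across probe sets. Genes are not independent replicates, so this value carries no test. The estimated prior had 1311 degrees of freedom against 1 residual one, so each standard error is close to a common trend (0.271 to 0.485, median 0.303) and hardly reflects the spread of the single probe set. Median centring over all probe sets left the median change of the 13648 tested 0.195 higher in experiment 2 than in experiment 1. The prior depended on this offset, but not on its size alone. With 1 array shifted so that the offset was 0, the prior had 14.3 degrees of freedom and the median standard error was 0.238. At an offset of 0.1 the prior had 14.6 degrees of freedom, and at -0.2 it had 9.63. With arrays centred on the kept probe sets the prior had 9.67 degrees of freedom (offset -0.0535), and with the values as deposited 9.05 (offset -0.213). Very small p-values in particular rest on this pooling.

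The fit was tested on simulated data for the KIN10 comparison, with 13648 probe sets of which 200 were changed. When all probe sets varied nearly alike (a prior of 1000 degrees of freedom), 38.0% of 2-fold and 97.8% of 4-fold changes were recovered, and 7.16% of calls were false. When probe sets varied unequally (a prior of 4 degrees of freedom), 1.6% of 4-fold and 13.2% of 8-fold changes were recovered, and 7.41% of calls were false, or 12.7% with an offset of 0.2 between the experiments. The list test called 1 of 400 random lists in each of these settings. The same 400 lists were drawn in every setting, so these are not separate checks. Simulated probe sets varied independently, so these runs do not test the preset correlation on genes that vary together. Far more probe sets were called in the data (30.2%) than were changed in the runs, so the recovered shares may not carry over.

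Probe sets were named through the platform annotation, with symbols updated by Entrez number in a RefSeq table of assembly TAIR10.1. A single gene name was found for 13513 probe sets, several for 503 and none in the tables used for 8730, and 13436 of the single names matched the RefSeq table. A symbol is used where there is one and the locus otherwise. Probe sets with several names were tested but not named. No probe set in these tables carried KIN10 as its single name, so its transcript level is not analysed here and the labels could not be checked against it.

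Before the data were examined, 27 gene lists with 439 entries were fixed, and 92 entries (21.0%) had a probe set with a single gene name. After the filter on low signals 78 were measured. The 10 lists with at least 3 measured members were tested with limma's camera (inter-gene correlation of 0.01), with 1 probe set per gene, the one with the highest mean signal. Members were also adjusted over the list alone, list medians were placed among 10000 random lists matched on mean signal in 20 bins, and camera with an estimated correlation and fry served as other list tests. The estimated correlation rests on 1 residual degree of freedom, so camera in this setting could hardly call any list or family. The genes named were also set by a rule fixed at that time: the 15 largest rises and 15 largest falls among called probe sets with 1 gene name and the same direction in both experiments, and up to 4 members per list with the smallest p. Other list members named, the probe sets without a gene name and the gene families were chosen after their values were seen.

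Alternatives were no block, the values as deposited, quantile and cyclic loess normalization, no filter or a filter at the 60th percentile, an offset of 17.5 (the 10th percentile of all signals) before log2, eBayes without the trend or with a robust prior, each array or experiment left out, and other thresholds. Centring on the 9 hybridization spike-in probe sets of the revised control design or on the kept probe sets alone, and the shift of the offset, were added after the data were seen. A scan of gene families by symbol stem was also added then. Figures were drawn with matplotlib 3.10.9.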

Results

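The study asked which transcripts change when KIN10 is expressed for 6 h in Arabidopsis mesophyll protoplasts. Control DNA and KIN10 were each measured on 2 arrays, with 1 array of each group per experiment. The design text calls the experiments biologically independent. Across probe sets, the log2 signals of the 4 arrays correlated with a Pearson r between 0.881 (control 1 with KIN10 2) and 0.932 (control 1 with control 2), and genes are not independent replicates.

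With KIN10, all 8 measured genes for the breakdown of amino acids rose. So did all 3 measured of the 19 listed as responding to sugar starvation, and 8 of 11 measured for autophagy. MCCA stands in both the amino acid and the sugar starvation list. Of the measured genes, 17 of 18 for ribosomal proteins and all 9 of ribosome assembly fell. These 5 lists were called by limma's camera with its preset correlation. None was called by camera with an estimated correlation (adjusted p from 0.561 to 0.572) or by fry (adjusted p from 0.0822 to 0.181). Both rest on 1 residual degree of freedom, which leaves little power, so neither decides whether these lists shifted. In all, 2006 probe sets were higher and 2111 lower with KIN10, which is 30.2% of the 13648 tested (limma, adjusted p under 0.05). Of these calls 4077 had the same direction in both experiments and 40 did not. On average at least 2-fold changes were seen for 1316 of the higher and 1406 of the lower probe sets. A single gene name was available for 1085 of the higher and 1168 of the lower ones. These counts depend on the experiment block, since without it 122 probe sets were higher and 51 lower. With 1 array left out and no block, 59 were higher and 26 lower without control 1, 88 and 8 without control 2, 697 and 172 without KIN10 1, and 128 and 358 without KIN10 2. No probe set used here has KIN10 as its single gene name, so the KIN10 transcript is not analysed here. On the scale of the hybridization spike-ins, 1275 were higher and 3858 lower (24.8% higher, against 48.7% after median centring).

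The largest rise among named genes was that of GAT1_2.1, a glutamine amidotransferase gene (AT1G15040), whose signal went from 55.0 to 8534 in experiment 1 and from 11.8 to 27939 in experiment 2. The control signal of 11.8 lies below the 10th percentile of its array (11.9), so the size of this rise is not well determined: the fold was 656 as computed and 361 with an offset of 17.5 added to each signal. MGL (AT1G64660), which encodes methionine gamma-lyase, rose 77.9-fold (log2 change 6.28 ± 0.30, SE, n = 2 arrays per group). Its log2 changes were 7.25 and 5.32 in experiments 1 and 2, further apart than this SE, which follows the common trend of all probe sets. MCCA, a subunit of the 3-methylcrotonyl-CoA carboxylase of leucine breakdown, rose 25.6-fold (4.68 ± 0.31), and BGLU46, a beta-glucosidase gene, rose 22.8-fold (4.51 ± 0.27). WES1 (GH3.5), which encodes an enzyme that joins auxin to amino acids, rose 18.9-fold on average (4.24 ± 0.31), with log2 changes of 3.11 and 5.37 in experiments 1 and 2.

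The other genes among the 15 largest rises carry only a locus name. AT4G25580 rose 54.8-fold, AT2G20670 54.6-fold, AT2G44380 49.1-fold, AT4G27450 37.6-fold, AT1G33055 28.3-fold and AT5G56100 26.4-fold. AT2G30600 rose 24.2-fold, AT1G23120 24.1-fold, AT4G32870 19.7-fold and AT1G76110 19.5-fold. AT2G20670 had about the same change in both experiments (log2 changes of 5.71 and 5.83), whereas AT1G33055 (2.24 and 7.41) and AT4G25580 (3.78 and 7.77) did not. For 11 of the 15 largest rises the folds in the experiments differed by more than 1.5 times. In 8 of the 15 genes a control signal lay below the 40th percentile of its array. With a robust prior in limma, GAT1_2.1 (adjusted p = 0.288), AT4G25580 (adjusted p = 0.370) and AT1G33055 (adjusted p = 0.493) were not called. Without the block, AT1G76110 (adjusted p = 0.0528) and WES1 (adjusted p = 0.0537) were not called by limma.

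The largest falls were smaller in size than the largest rises. AT3G43270, a pectinesterase gene, was 9.89-fold lower with KIN10 (log2 change -3.31 ± 0.29, SE, n = 2 arrays per group), with signals of 17742 and 1117 in experiment 1 and 3035 and 420 in experiment 2. AT5G53750 was 9.84-fold lower, SBT3.3, a subtilisin-like protease gene, 9.64-fold, and AT2G39795 9.55-fold. Genes for the methyltransferases that make methyl jasmonate and methyl salicylate were among these falls, with JMT 9.17-fold lower (-3.20 ± 0.41) and BSMT1 7.17-fold lower (-2.84 ± 0.43). In experiments 1 and 2 the log2 changes were -4.26 and -2.13 for JMT and -4.17 and -1.51 for BSMT1. AT1G15250, a gene for ribosomal protein L37 of the large subunit, was 9.03-fold lower on average, with log2 changes of -5.19 and -1.16 in experiments 1 and 2, and AT5G60670, a gene for ribosomal protein L12, was 6.60-fold lower. AT3G20240 was 7.95-fold lower, AT3G22660 7.91-fold, AT1G34350 7.18-fold, AT2G42710 6.80-fold, AT3G58660 6.76-fold and AT3G10530 6.59-fold. AT5G20700 had a log2 change of -2.81 ± 0.29.

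In 9 of the 15 genes with the largest falls, a KIN10 signal lay below the 40th percentile of its array, so these folds are less certain than the direction, and for 13 of the 15 the folds in the experiments differed by more than 1.5 times. In limma with a robust prior AT1G15250 (adjusted p = 0.525) and AT3G22660 (adjusted p = 0.270) were not called. Without the block those 2 genes and AT1G34350, BSMT1, AT5G20700 and AT5G60670 were not called (limma adjusted p from 0.0528 to 0.162).

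**Figure D1:**
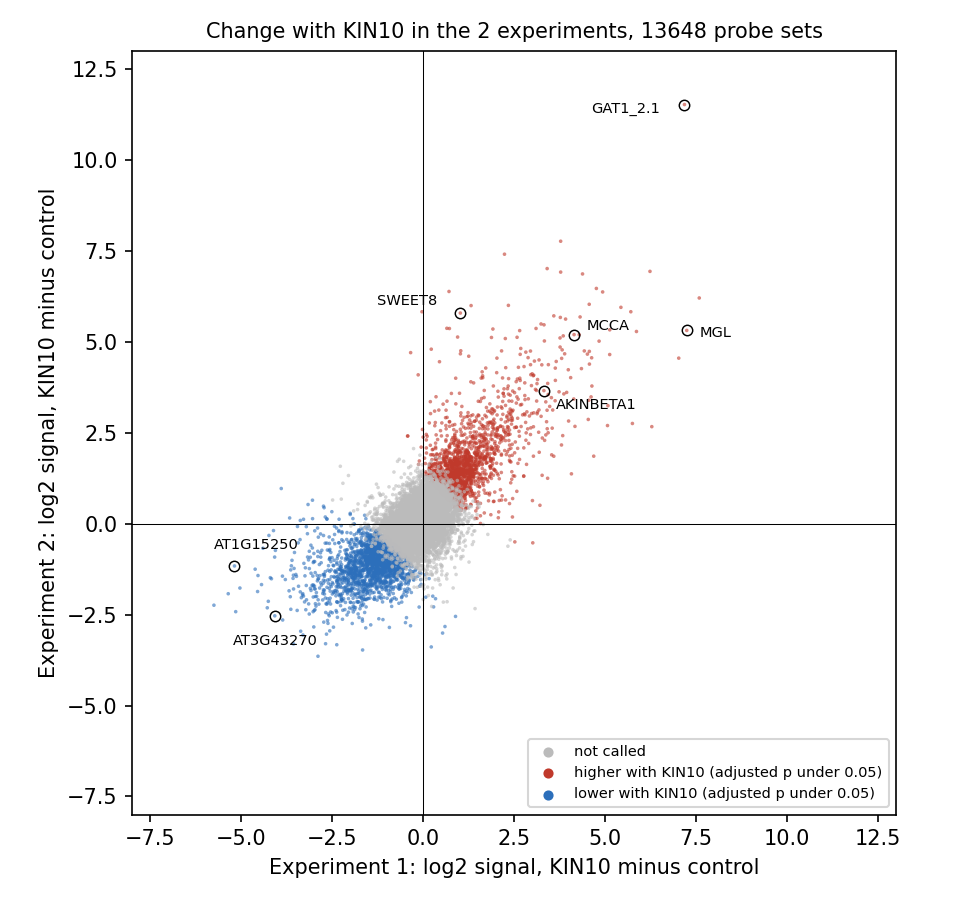
Log2 change in signal (KIN10 minus control, median-centred arrays) in experiment 1 on the x axis and experiment 2 on the y axis, 1 point per tested probe set, with called probe sets in red (2006 higher) and blue (2111 lower) and a few genes circled. The changes correlated across probe sets with a Pearson r of 0.775, and most called points lie in the quadrants where both experiments have the same sign.

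The experiments gave similar changes. Across the 13648 probe sets the changes in experiment 1 and experiment 2 correlated with a Pearson r of 0.775 and a Spearman rho of 0.740, and genes are not independent replicates. At least 2-fold changes in the same direction in both experiments were found for 1732 probe sets, 859 higher and 873 lower, and 6 probe sets changed at least 2-fold in opposite directions. In experiment 1 alone, 1047 probe sets were at least 2-fold higher and 1759 lower, and in experiment 2 alone, 1874 were higher and 1322 lower. Among probe sets with no gene name in the tables used, the largest called rises were 120-fold and 96.3-fold, the largest called fall had log2 changes of -5.75 and -2.24 in experiments 1 and 2, and the next was 13.8-fold lower on average.

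All 8 measured genes of amino acid catabolism rose, with a median log2 change of 2.77. They include both subunits of 3-methylcrotonyl-CoA carboxylase (MCCA, and MCCB at 8.19-fold) and isovaleryl-CoA dehydrogenase (IVD, 10.2-fold), which act in leucine breakdown, and AT4G33150, which encodes the enzyme that starts lysine breakdown (7.84-fold). ETFQO, which passes electrons to ubiquinone, rose 5.95-fold, and the valine-pathway dehydrogenase gene ALDH6B2 rose 4.53-fold. AT2G26800 (1.98-fold) and D2HGDH (1.83-fold) rose least. Adjusted over the list alone the count was also 8. The list was higher than other genes (limma camera, adjusted p = 7.31e-10), and had an adjusted p = 0.572 with an estimated correlation. Without the block, 7 of the 8 were not called by limma (adjusted p from 0.0927 for IVD to 0.754). With 1 array left out and no block, the list median ran from 1.42 (without KIN10 replicate 2) to 4.05 (without KIN10 replicate 1).

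The sugar-starvation and dark-induced list had 3 measured genes, and all of them rose, also when adjusted over the list alone. AT3G15450 rose 15.7-fold (log2 change 3.98 ± 0.34). The other members stand in a further list each, MCCA in amino acid catabolism and AKINBETA1 in the SnRK1 list. AKINBETA1, a regulatory subunit of SnRK1, rose 11.2-fold (3.49 ± 0.33). The median log2 change was 3.98 (limma camera, adjusted p = 6.86e-08), with an adjusted p = 0.561 with an estimated correlation. In the SnRK1 list of 3 measured genes AKINBETA1 was the only call, also when adjusted over the list alone. AT4G16360 (-0.40 ± 0.28) and AT2G28060 (0.30 ± 0.28), the genes of the other beta subunits, were not called, and nor was the list (limma camera, adjusted p = 0.140). On the spike-in scale AT4G16360 was called lower (log2 change -0.73, limma adjusted p = 0.0180). Without the block, AKINBETA1 had an adjusted p = 0.0559 in limma.

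Of 11 measured genes of autophagy, 8 rose, 3 were not called and none fell, and 10 rose when adjusted over the list alone. Most of them encode ATG8, the small protein that is joined to the autophagosome membrane. ATG8H rose 4.74-fold (log2 change 2.24 ± 0.33), ATG8E 3.93-fold, ATG8F 3.57-fold and ATG8B 3.02-fold. ATG3, the enzyme that attaches ATG8 to lipid, rose 2.01-fold. ATG8D had a log2 change of 0.48 ± 0.31 and was not called. The median change of the list was 1.17 (limma camera, adjusted p = 1.32e-05), with an adjusted p = 0.572 with an estimated correlation. Without the block none of the 8 was called (limma adjusted p from 0.243 to 0.732).

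Of 18 measured genes for cytosolic ribosomal proteins, 17 fell, 1 was not called and none rose, and all 18 fell when adjusted over the list alone. AT2G44120 (RPL7C) was 4.05-fold lower (log2 change -2.02 ± 0.33), AT3G02560 (RPS7B) 3.64-fold, AT5G07090 (RPS4B) 3.19-fold and AT5G39850 (RPS9C) 3.05-fold. AT1G48830 (RPS7A) had a log2 change of -0.68 and was not called over all probe sets. The list median was -1.35 (limma camera, adjusted p = 1.06e-08), with an adjusted p = 0.572 with an estimated correlation. The median was -1.72 in experiment 1 and -1.06 in experiment 2. Without the block none of the 17 was called (limma adjusted p from 0.255 to 0.772).

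All 9 measured genes of ribosome biogenesis fell, also when adjusted over the list alone. AT1G52930 (BRX1-2) was 3.92-fold lower, AT5G14520 (PES, needed for the large subunit) 3.91-fold, and the small nucleolar particle genes AT5G08180 (NHP2) and AT3G05060 (NOP58B) 3.77-fold and 3.67-fold. IMP4 fell least, by 0.96 on the log2 scale. The list median was -1.71 (limma camera, adjusted p = 5.42e-08), with an adjusted p = 0.561 with an estimated correlation. Without the block none of the 9 was called (limma adjusted p from 0.0783 to 0.667).

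**Figure D2:**
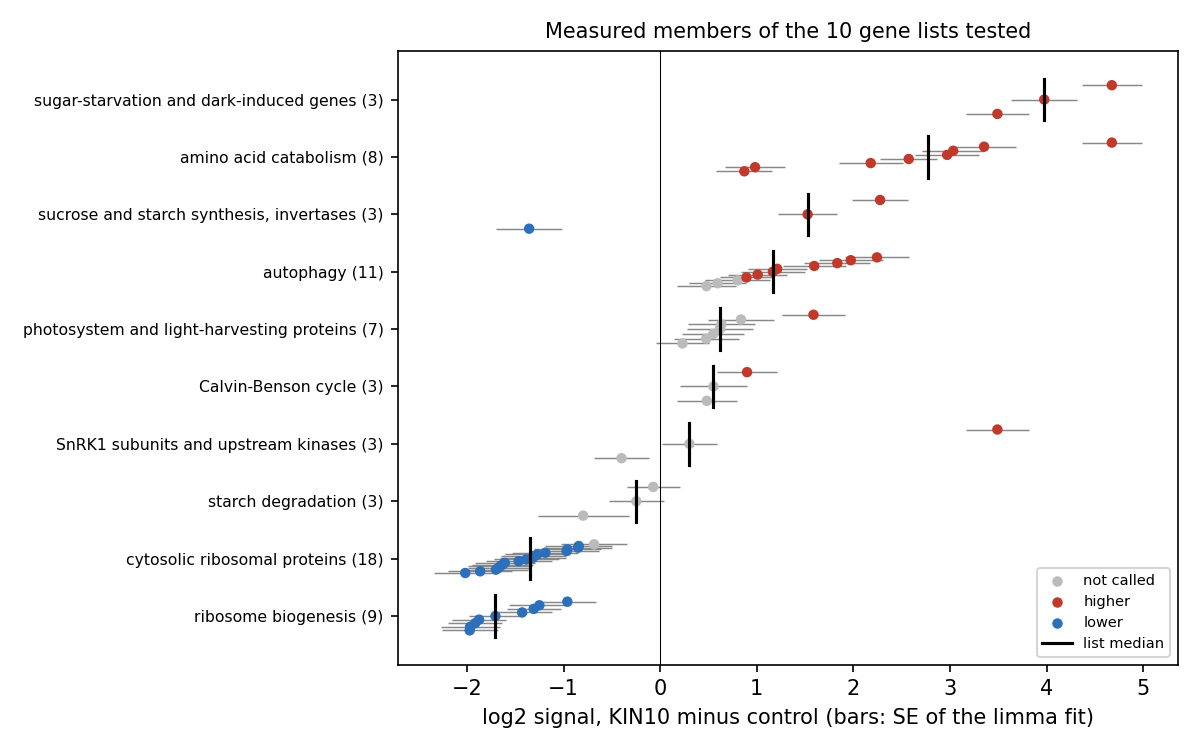
Log2 change in signal with KIN10 (x axis, KIN10 minus control) for each measured gene of the 10 lists tested, with the standard error of the limma fit as bars, calls in red (higher) or blue (lower) and a black line at the list median. All 8 genes of amino acid catabolism lie above 0, and all 18 genes for cytosolic ribosomal proteins and 9 of ribosome biogenesis lie below 0.

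Carbohydrate genes went both ways. ATSPS4F, a sucrose phosphate synthase gene, rose 4.85-fold (log2 change 2.28 ± 0.29) and the vacuolar invertase gene AT1G62660 rose 2.88-fold, whereas APL3, a large subunit of ADP-glucose pyrophosphorylase in starch synthesis, was 2.56-fold lower. These are all 3 measured genes of the list for sucrose and starch synthesis and invertases, and the counts were the same when adjusted over the list alone. The list was not called (limma camera, adjusted p = 0.140) except without control replicate 2 and the block (adjusted p = 0.0272). Without the block none of these 3 genes was called (limma adjusted p from 0.128 to 0.384). None of the 3 measured genes of starch degradation was called, over all probe sets or adjusted over the list alone. DPE1 had a log2 change of -0.80 ± 0.47, PWD -0.25 ± 0.29 and AMY1 -0.07 ± 0.27, and the list was not called (limma camera, adjusted p = 0.497).

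Among genes of photosynthesis 1 of each list was called, and calls depended on the scaling and the variance model. PSAN, a subunit of photosystem I, rose 3.00-fold (log2 change 1.59 ± 0.33), and the other 6 of 7 measured genes for photosystem and light-harvesting proteins were not called, also when adjusted over the list alone. PSAE-1 had a log2 change of 0.84 ± 0.34, LHCB4.1 0.63 ± 0.35 and PSBW 0.62 ± 0.34. The list had a median change of 0.62 and was not called (limma camera, adjusted p = 0.0687). It was called with the values as deposited (median 0.50, adjusted p = 0.00200) and after quantile (0.00881) or cyclic loess normalization (0.00699). Centring on the kept probe sets (0.00530) and no filter (0.0498) called it too. Other settings did not, such as the spike-in scale (limma camera, adjusted p = 0.0876) and the fit without the block (0.134). With 1 array left out and no block, its median ran from -0.018 (without KIN10 replicate 2) to 1.51 (without KIN10 replicate 1). On the median-centred values this list had an adjusted p = 0.572 with an estimated correlation in camera of limma. In the Calvin-Benson cycle PRK, phosphoribulokinase, rose 1.87-fold (0.90 ± 0.31). RCA (0.55 ± 0.35) and SBPASE (0.48 ± 0.31) were not called, also when adjusted over the list alone. This list was not called (limma camera, adjusted p = 0.202), but was with the values as deposited (adjusted p = 0.0433), and on the median-centred values it had an adjusted p = 0.572 with an estimated correlation. With 1 array left out and no block, its median ran from -0.22 (without KIN10 replicate 2) to 1.32 (without KIN10 replicate 1). As deposited, PSAE-1 (limma adjusted p = 0.00275), LHCB4.1 (0.0223), PSBW (0.0382) and RCA (0.0333) were called higher too. Their changes were smaller as deposited (0.72 for PSAE-1), but the prior had 9.05 degrees of freedom instead of 1311. With a robust prior, PSAE-1 was called on the median-centred values as well (limma adjusted p = 0.0317). Without the block PSAN (adjusted p = 0.619) and PRK (adjusted p = 0.845) were not called by limma, and on the spike-in scale PRK was not called either (limma adjusted p = 0.0993).

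A further 8 lists had 1 or 2 measured genes and were not tested. WES1, the measured gene of early auxin response, rose as given above. COR47, a dehydrin gene of the abscisic acid list, rose 2.85-fold (log2 change 1.51 ± 0.34), although without the block it was not called (limma adjusted p = 0.562), and COR15A had a change of 0.25 ± 0.30. The values of the others, none of them called, were 0.40 ± 0.34 for AIM1 of fatty acid beta-oxidation, 0.00 ± 0.34 for EXPA15 of the cell wall list, and 0.53 ± 0.32 for BZIP53 of the bZIP factors. UF3GT (-0.27 ± 0.43) and UGT78D2 (0.05 ± 0.27) stood for flavonoid synthesis and GI (0.53 ± 0.27) for the clock. FMA, a guard cell marker, had a change of -0.45 ± 0.37. Adjusted over the list alone, WES1 and COR47 were again the calls. For 9 lists no gene has a value here. No probe set with a single gene name was found for trehalose metabolism, nitrogen assimilation, heat shock, jasmonate, salicylate and pattern-triggered defence, epidermis and phloem. Probe sets without a single name may still cover these genes, which was not checked. The named members of the lists for type-A response regulators (2) and trichomes (1) were removed by the filter on low signals.

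The array's own control probe sets moved with the groups too. After median centring, 5 of the 6 actin probe sets and all 5 GAPDH probe sets were lower with KIN10 in both experiments, with class medians of -0.94 and -0.47 for actin and -0.91 and -0.25 for GAPDH in experiments 1 and 2. The exception was a 5' actin probe set of the older control design (0.30 and 1.36). All 5 polyubiquitin probe sets were higher in both experiments (medians 0.30 and 0.76), but on the scale of the hybridization spike-ins their median in experiment 1 was -0.0045. The older GAPDH 5' probe set was lower by 1.31 and 0.69 more than its 3' partner. These values come from 1 array per group in each experiment and were not tested.

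**Figure D3:**
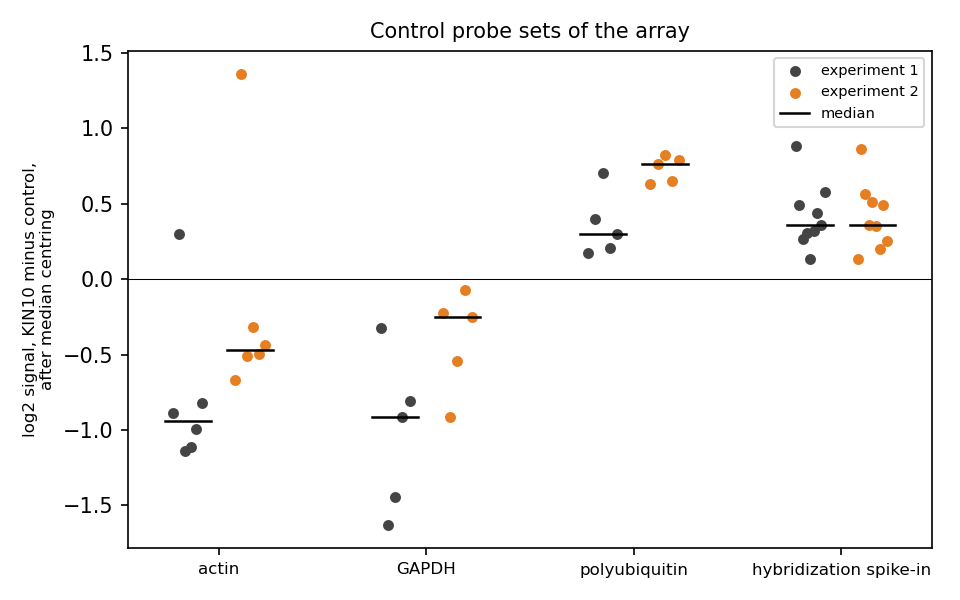
Log2 change in signal (y axis, KIN10 minus control, median-centred arrays) of the array's actin, GAPDH, polyubiquitin and (revised design) hybridization spike-in probe sets, 1 point per probe set in experiment 1 (grey) and experiment 2 (orange), with black lines at the medians. Polyubiquitin medians are 0.30 and 0.76 here, and on the spike-in scale the first becomes -0.0045, while actin and GAPDH medians are below 0 on both scales.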

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

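Both results below come from control probe sets that the gene comparison does not use, and after median centring the class medians of both (for the spike-ins, over the revised control design) were higher with KIN10 than with control DNA in each experiment. The tests in this part were all chosen after the result was seen, and the test of 5' ends was at first limited to the revised actin and GAPDH pairs and widened once the older GAPDH pair was seen.

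The polyubiquitin control probe sets had a median log2 change of 0.55 (all 5 higher in both experiments), while 5 of 6 actin and all 5 GAPDH ones were lower, but on the spike-in scale the polyubiquitin median was -0.0045 in experiment 1. The gap between these medians was 1.21 in experiment 1 and 1.2 in experiment 2. This argues against the single scaling factor per array as the cause of the gap, since such a factor moves all probe sets alike. The gap does not decide whether polyubiquitin itself was higher. A factor can move that median, as the spike-in scale did in experiment 1. For actin, the revised pair argues against loss of the 5' ends of transcripts in the KIN10 samples. Its 5' probe set fell by at most 0.178 beyond the 3' one. The older actin pair went the other way (-1.19 and -2.03). Its 5' probe set rose (0.30 and 1.36) while the other 5 actin probe sets fell, so this pair carries no weight here. Loss of 5' ends has no bearing on the higher polyubiquitin signals. For GAPDH it stays open: the older 5' probe set fell by 1.31 and 0.69 beyond the 3' one, but the revised pair differed by at most 0.18. An effect of KIN10 stays open and was not tested beyond the comparison itself.

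The hybridization spike-ins, bacterial and phage transcripts added to the labelled sample, had a median log2 change of 0.42 over the 9 probe sets of the revised design, all of them higher in both experiments after median centring. As deposited, 6 of these 9 were higher in both, and the class median was 0.45 in experiment 1 and 0.04 in experiment 2. Of the 9 spike-in probe sets of the older design 7 were higher in both experiments, 1 was lower in both and 1 went both ways after median centring (median 0.35), and as deposited their median was 0.56 in experiment 1 and -0.17 in experiment 2.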

How the results depend on the processing

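Centring on the spike-ins or on the kept probe sets was chosen after the data were seen, and the other alternatives before. With no replicate block, 122 probe sets were higher and 51 lower, all 173 of them called with the block too, and 23 of the 53 called named genes stayed called. Leaving out 1 array, without the block and with the lone array assumed to vary like the others, gave 59 to 697 higher and 8 to 358 lower: 59 and 26 without control replicate 1, 88 and 8 without control replicate 2, 697 and 172 without KIN10 replicate 1, and 128 and 358 without KIN10 replicate 2. Fits without the block ignore the pairing, so differences between the experiments enter the residual spread. Same-numbered arrays did deviate together from their group means (Pearson r of 0.705 across probe sets). The fits with 1 array left out also use fewer arrays, and how much each step contributed was not separated. A floor of 2-fold left 1316 and 1406. Spike-in centring gave 1275 higher and 3858 lower, since it moved the median change of all tested probe sets to -0.30, against 0.03 after median centring and -0.08 as deposited (a shift of 0.11). Between 1587 and 2270 were higher and between 1484 and 2510 lower under the other scalings, filters, offset and variance models. Probe sets at least 2-fold apart in the same direction in both experiments numbered 2740 with no filter (653 in opposite directions), and 3700 at 1.5-fold and 635 at 3-fold. The 5 called lists kept their call in all 14 fits with other scalings, filters or probe set choices, with no block or with an array left out (the variance models do not enter camera and are not counted), with median changes such as 0.42 to 1.69 for autophagy and -1.92 to -0.84 for ribosomal proteins, and highest camera adjusted p in limma from 0.000299 (ribosome biogenesis) to 0.0421 (autophagy). With camera's estimated correlation 0 lists were higher and 0 lower, likewise with fry (0 and 0, lowest limma fry adjusted p = 0.0822, lowest unadjusted p = 0.00822), and as deposited 5 were higher. The estimated correlation rests on 1 residual degree of freedom (values from -0.333 to 1 over the lists), which leaves camera little power in that setting. The fry test rests on the same 1 residual degree of freedom, so its power is low as well. For the values as deposited the cause was not tested. PRK turned to -0.0758 without control replicate 1 and -0.0470 without KIN10 replicate 2, both without the block, and the other 52 called named genes kept their sign in every fit with a test. The robust prior ended 5 calls among named genes. Each experiment on its own gives values for genes and lists but no test and no count of calls. A random block was not run, since limma gave no estimate of the correlation with 4 arrays, and the KIN10 transcript has no value here. Signal over background limits the largest folds.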

Other observations

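Other gene families were looked at after the data were seen, in a scan of 40 groups of genes that share a symbol stem, plastid-encoded genes included. The 4 measured histone H2B genes all rose, HTB11 by 3.18-fold, HTB2 by 2.39-fold, HTB1 by 2.35-fold and HTB4 by 1.97-fold, in both experiments and under all 5 other scalings (family medians from 0.91 on the spike-in scale to 1.29). The family was called (limma camera, adjusted p = 0.0312), with an adjusted p = 0.966 with an estimated correlation. The linker histone gene HIS1-3 (5.09-fold) and HON4 (5.22-fold) rose as well, and the H3 variant gene HTR12 was not called (log2 change 0.92 ± 0.45). Without the block the 4 H2B genes, HIS1-3 and HON4 were not called (limma adjusted p from 0.0734 to 0.745). The 68 plastid-encoded genes had a median change of 0.41, with 4 higher and 6 lower, and were not called as a group (limma camera, adjusted p = 0.265).

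Of 6 measured sugar transporter genes of the SWEET family 2 rose, 1 fell and 3 were not called, and of 6 glutathione transferase genes of the tau class 1 rose, 2 fell and 3 were not called. Neither family was called (limma camera, adjusted p = 0.602 for each), and the genes named here kept their direction under all 5 other scalings. SWEET2 rose 13.6-fold (log2 changes of 3.06 and 4.47 in the experiments) and SWEET8 10.6-fold (1.02 and 5.79), while SWEET17 was 4.32-fold lower (-2.26 and -1.96). GSTU25 was 4.60-fold and GSTU22 2.59-fold lower, whereas GSTU18 rose 1.80-fold. COR27, a cold-regulated gene, rose 5.25-fold. SWEET8 was not called by limma with a robust prior (adjusted p = 0.569), and of these genes only SWEET2 was called without the block (limma adjusted p = 0.0484, range of the others 0.0598 to 0.594).

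For the patterns that follow, the brightness tests were chosen after the result was seen, along with the spike-in scale, and the length, offset and signal floor tests before. Of the measured genes, 17 of 18 for ribosomal proteins and 9 of 9 for ribosome biogenesis were called lower with KIN10, while neither list was called with an estimated correlation (limma camera, adjusted p = 0.572 and 0.561). Probe set brightness is argued against as the cause, since both list medians lay at the percentile of 0 among 10000 lists matched on mean signal. Short genes are argued against too: the ribosome biogenesis genes are not short (median 2543 bp, against 2340 bp for all genes and 1854 bp for ribosomal protein genes), and among 10000 lists matched on gene length both medians again lay at the percentile of 0, and the lowest matched medians were -0.85 and -1.30 against -1.35 and -1.71. All 27 genes had a length. An effect of KIN10 stays open and was not tested beyond the comparison itself.

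After median centring, falls outnumbered rises in experiment 1 (37.3% rises among probe sets at least 2-fold apart). In experiment 2 rises outnumbered falls (58.6% rises). On the spike-in scale falls outnumbered rises in both experiments (19.1% and 31.7% rises). So they did after each experiment was shifted to a median change of 0 (42.4% and 48.2% rises). A scaling offset and a lower signal floor in experiment 2 both stay open. Shifting each experiment to a median change of 0 left a difference of 5.79 points, but such a shift in itself balances rises and falls, and on the spike-in scale the shares differed by 12.6 points. Among the 4550 brightest kept probe sets the difference was 30.2 points. This test was planned to decide on a floor but does not do so, since a floor moves the array medians used for centring. After a shift within these probe sets the shares were 48.9% and 49.2%, but this shift too balances rises and falls in itself and decides nothing. No biological explanation was tested, because operator, plants and facility changed together with the experiment.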
